A study of Homo sapiens with 6 samples.

How the data were processed

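Poly(A) RNA of A549 cells was measured by paired-end RNA sequencing in 6 samples, 3 treated with rhSP-D at 10 µg/ml and 3 given elution buffer as vehicle, each for 48 h. Per the labels' protocols, libraries were made with an NEBNext Ultra RNA kit after Trizol extraction. Per the submitters' processing notes, cutadapt, STAR 2.7.0a and featureCounts 2.0.0 were used with the human build GRCh38 (hg38); the trimming settings, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited whole-number counts per gene, not normalized, for 57773 Ensembl genes in a table of the 6 samples. Of these genes 52338 have an identifier in GENCODE 29, whose GRCh38 coordinates and exon lengths are given here. They need not match the authors' annotation, whose symbols include older names such as CTGF for CCN2. Of 103 genes set by rule to be named, 99 were in GENCODE 29, and 35 overlap an exon of the opposite strand, whose reads cannot be told apart if strand was not counted.

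Samples were grouped by their titles. Triplicate treatment is stated, but no source used here says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical; the biological coefficient of variation was 2.51%. Total counts ranged from 11396193 to 26030880. Chi-square per degree of freedom between pairs of libraries was 1.92 to 2.15 within groups and 3.90 to 6.15 between groups, so no library was a copy of another. The 10 most abundant genes took 8.29 to 8.38% of counts and mitochondrially encoded genes 7.74 to 7.78% in vehicle and 7.81 to 7.88% in rhSP-D. The first principal component (29.3% of variance) set vehicle replicate 1, the shallowest library, apart at -38.2, with the others at 3.59 to 12.3.

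Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM factors, and a robust quasi-likelihood fit was tested 2-sided with Benjamini-Hochberg adjustment over 15848 genes. A gene was said to have changed, risen or fallen at an adjusted p under 0.05. Fold changes are rhSP-D over vehicle, with the SE taken from the test statistic, and CPM are counts scaled to the TMM-normalized library size, with means, SDs and n = 3. Floors of 3 counts and 95% intervals cover counting error or the fitted spread only.

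Before the data were examined, 39 gene lists were fixed, covering IL-4 and STAT6 signalling, SP-D binding proteins, lung cell types, growth factor response, cell cycle, p53, apoptosis, epithelial and mesenchymal genes, matrix, TGF-beta, YAP/TAZ, inflammation, interferon, antigen presentation, complement, stress responses, zinc, lipid and energy metabolism, ribosomal proteins, histones, and markers of macrophages, lymphocytes, fibroblasts and endothelium. Of their entries 650 were matched and 6 were not. The 36 lists with 3 or more tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists; list p-values in the text are from this test unless an estimated correlation is named. At the preset value 17 lists passed, 11 up and 6 down, and with an estimated correlation 0 passed. Counts adjusted over the list alone use Benjamini-Hochberg adjustment within each list.

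Genes to be named were set by rule before the data were examined: SFTPD, STAT6 and IL4R; the 10 largest rises and 10 largest falls among changed genes with a mean of at least 1 CPM whose 3 rhSP-D values all lay on one side of the 3 vehicle values; and the 3 members with the smallest p of each list that passed or held 3 or more changed genes. Some genes that met this rule are not reported here. Members named to spell out a small count, and the genes past a minimum fold of 1.2, were chosen after their values were seen.

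The alternatives were DESeq2 size factors, upper-quartile factors and library totals alone; no filter on low counts and a filter of 1 CPM in 3 samples; a replicate block; each library left out in turn; DESeq2 1.42.0 and limma-voom; mitochondrially encoded genes left out; thresholds of adjusted p under 0.01, of a 1.5-fold change and a test against a fold of 1.2; and camera with an estimated correlation and fry. A correction for gene length and GC content, and thinning of all libraries to the depth of the shallowest, were added after seeing the data, as was the correction together with an estimated correlation. The correction fits natural splines with 5 degrees of freedom on transcript GC and log2 exonic length to each library and enters them as offsets, for genes in GENCODE 29 (96.8% of those tested). Exonic length is that of the merged exons of all transcripts of a gene, and GC content is that of its longest transcript.

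The procedure was tested on simulated data of the comparison of rhSP-D with vehicle over 15640 genes. It recovered 14% of genes changed 1.1-fold, 44% at 1.2-fold, 86% at 1.5-fold and 82% at 2-fold. With a simulated length and GC trend 568 of 15424 unchanged genes were called without the correction, and 2 of 14944 with it. That trend was built on the same length and GC measures that the correction fits, and was the same in every rhSP-D library. The simulation therefore does not cover trends of another form. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.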

Results

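RNA sequencing counts were compared between A549 cells treated with recombinant human surfactant protein D (rhSP-D) and A549 cells given vehicle. A549 is a human lung adenocarcinoma line with features of alveolar epithelium. Surfactant protein D is a collectin, a soluble carbohydrate-binding protein of innate immunity that alveolar type II cells secrete into the airspace. The treated group received 10 µg/ml for 48 h, the vehicle group received an equal volume of the buffer in which the protein had been eluted, and each group held 3 samples. Total counts over genes were 11396193, 17760075 and 19803697 in vehicle replicates 1, 2 and 3, and 26030880, 18599955 and 20232050 in rhSP-D replicates 1, 2 and 3.

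The comparison of rhSP-D with vehicle asked which transcripts of these lung cancer cells differed after exposure to the protein, with attention to interleukin-4 (IL-4) and STAT6 signalling, which the title of the series names. Genes of zinc handling changed: SLC39A10, a zinc importer, rose by 69.6%, while the metallothionein MT2A fell by 23.6% and the zinc exporter SLC30A1 fell by 20.4% (log2 changes 0.76, -0.39 and -0.33, each with an SE of 0.03 or 0.04, n = 3 per group). All 26 ribosomal protein genes of the list rose, with a median log2 change of 0.17, and 19 of 22 nuclear genes of oxidative phosphorylation rose, with a median of 0.16. Of 12 genes of fatty acid synthesis 7 fell, as did the secreted mucins MUC5AC and MUC5B; 8 of 18 genes of NF-kB signalling rose and 2 fell, and 8 of 13 genes of antigen presentation rose. With the correlation between genes estimated from the data no list passed, though 7 did, just under the threshold, once trends on gene length and GC content were removed as well: ribosomal proteins, nuclear oxidative phosphorylation, fatty acid synthesis, airway secretory genes, TGF-beta targets, complement and coagulation, and EGFR and ERK genes. STAT6 and IL4R did not pass the test.

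Of 15848 genes tested, 2526 changed (15.9%), of which 1475 were higher and 1051 lower in rhSP-D, so that 58.4% of the changed genes were higher. Scaling by library totals alone gave 856 higher and 1961 lower, or 30.4% higher. Most changes were small: the median fold was 1.12 among the genes that rose and 0.876 among those that fell, 28 genes rose and 42 fell by 1.5-fold or more, and 11 rose and 13 fell by 2-fold or more. The 3 rhSP-D values lay wholly above or below the 3 vehicle values for 2453 of the 2526 changed genes, and for 31.5% of all genes tested, against 10% by chance; of the changed genes named below, CENPE was the exception. The count was 1678 without rhSP-D replicate 1, the deepest library, and 1437 after correction for trends on gene length and GC content that separated the groups.

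A test against a minimum fold of 1.2 left 6 genes, named here after their values were seen. Of these, 3 were higher: SLC39A10, RHCG, which encodes an ammonium transporter and rose by 55.7%, and AC011933.1, which rose by 48.9%. The other 3 were lower: the metallothionein MT1X, the pseudogene ITGB1P1, which fell by 38.9%, and the antisense RNA RP11-611O2.5. RP11-611O2.5 had 38 counts over the vehicle group and 0 over the rhSP-D group, at least 16.3-fold lower against a floor of 3 counts over the group. Its exons overlap exons of the opposite strand over 785 of 785 nt, so its reads cannot be told apart if strand was not counted. Reads of ITGB1P1 can be shared with ITGB1, an integrin gene measured at 1546 ± 4.18 CPM in vehicle and 1543 ± 24.9 CPM in rhSP-D (SD, n = 3).

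RNA of the pathway named in the title did not pass the test. STAT6 (ENSG00000166888, chromosome 12, 57095408 to 57132139) was measured at 94.96 ± 1.13 CPM in vehicle and 96.9 ± 2.41 CPM in rhSP-D (SD, n = 3), a log2 change of 0.03 ± 0.03 (SE, adjusted p = 0.618) with a 95% interval from -2.6% to 6.9%. IL4R (ENSG00000077238, chromosome 16, 27313668 to 27364778), the receptor subunit that binds IL-4, was at 83.8 ± 1.36 and 85.1 ± 2.86 CPM, a log2 change of 0.02 ± 0.04 (SE, adjusted p = 0.757) with an interval from -3.5% to 6.7%. Among 13 tested genes of IL-4, IL-13 and STAT6 signalling 1 rose, TGM2, by 3.76%, and the same gene was the only one adjusted over the list alone. Others of the 23 genes of the list, among them ALOX15, POSTN, SERPINB2 and CLCA1, were too scarce to test, so the result does not cover them. The median of the list was -0.03 (adjusted p = 0.672, and adjusted p = 0.834 with an estimated correlation), and it ran from -0.037 to 0.003 with 1 library left out. These are RNA levels, and phosphorylation of STAT6 was not analysed here. SFTPD, the gene of surfactant protein D itself, had 6, 14 and 13 counts in vehicle and 24, 10 and 11 in rhSP-D (log2 change 0.07 ± 0.38 SE, adjusted p = 0.938), with an interval from -39.1% to 80.9%, so no difference was detectable at this depth.

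All 5 tested genes of the metallothionein and zinc list changed, 1 higher and 4 lower, with the same counts adjusted over the list alone. SLC39A10 (ENSG00000196950, chromosome 2, 195575977 to 195737702) went from 52.1 ± 3.54 CPM in vehicle to 88.5 ± 2.504 CPM in rhSP-D (SD, n = 3), a log2 change of 0.76 ± 0.04 (SE, adjusted p = 1.92e-12). MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497), which encodes a metal-binding protein induced by zinc, went from 142 ± 4.26 to 108 ± 2.48 CPM, a log2 change of -0.39 ± 0.03 (SE, adjusted p = 4.20e-10). SLC30A1 (ENSG00000170385, chromosome 1, 211571568 to 211578742) went from 122 ± 2.42 to 96.8 ± 2.23 CPM, a log2 change of -0.33 ± 0.03 (SE, adjusted p = 1.24e-08). MT1X fell by 38.1% and MT1F fell by 48.2%, the latter from a mean of 4.40 CPM in vehicle. The list fell relative to other genes, with a median of -0.39 (adjusted p = 0.00362), a call lost with an estimated correlation (adjusted p = 0.103). Metallothionein genes are similar in sequence, so counts of the single members are uncertain.

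**Figure D1:**
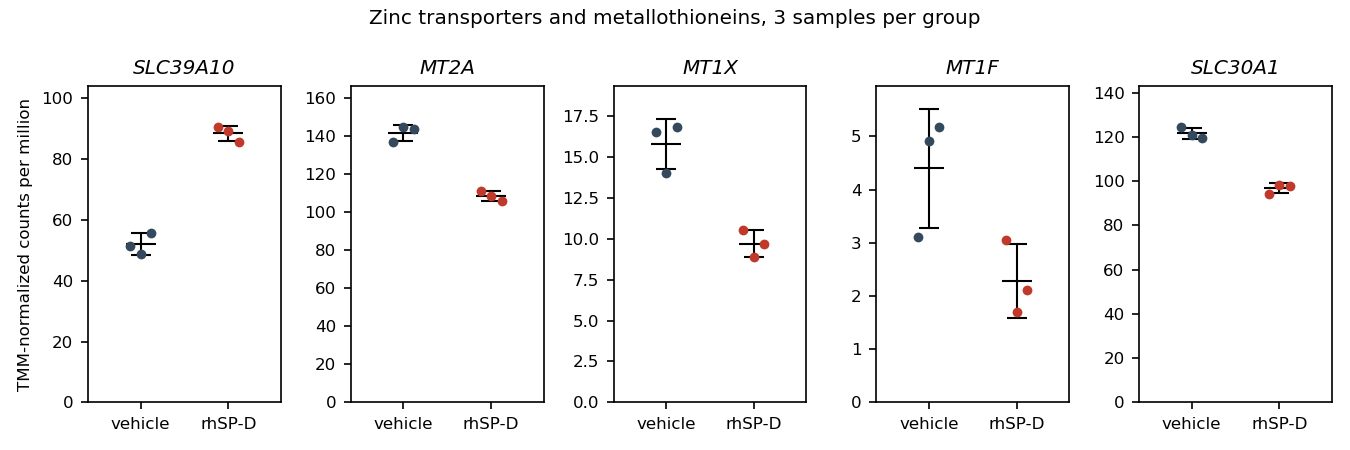
TMM-normalized CPM of 5 genes of zinc handling in 3 vehicle and 3 rhSP-D samples; points are samples, and bars are the mean ± SD. SLC39A10 was higher in all 3 rhSP-D samples than in any vehicle sample, and MT2A, MT1X, MT1F and SLC30A1 were lower.

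Transcripts of ribosomal proteins rose together. Each of 26 tested ribosomal protein genes was higher, also adjusted over the list alone, among them RPS19 by 16.7% (log2 change 0.22 ± 0.02 SE), RPS3 by 15.8% and RPL8 by 13.1%. The list made up 2.60 ± 0.03% of counts in vehicle and 2.84 ± 0.02% in rhSP-D (SD, n = 3). It was higher than other genes (adjusted p = 2.61e-58, but adjusted p = 0.0646 with an estimated correlation). Once trends on length and GC content were removed, 22 of the 26 were still higher, with a median of 0.13; RPL8 was then at a log2 change of 0.06, against 0.18 before. The list then passed also with an estimated correlation, just under the threshold (adjusted p = 0.0484). Ribosomal protein genes have many processed pseudogenes that can share their reads.

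Genes of energy metabolism rose in part. Of 22 nuclear genes of oxidative phosphorylation 19 rose (21 adjusted over the list alone) and none fell, with COX4I1, COX6A1 and COX7C, subunits of cytochrome c oxidase, up by 14.7%, 14.5% and 14.4%. The list passed at adjusted p = 6.95e-20, and at adjusted p = 0.0702 with an estimated correlation it did not; 12 of its genes were higher after removal of the length and GC trends, with a median of 0.10. Among 13 mitochondrially encoded genes 8 rose (8 up and 1 down adjusted over the list alone), including MT-ND3 by 14.97%, MT-CYB by 9.72% and MT-CO3 by 9.01%, and the list passed at adjusted p = 5.02e-08 (adjusted p = 0.0702 with an estimated correlation). That call ended and the median turned from 0.10 to -0.005 when the trends were removed (adjusted p = 0.842), and MT-CO3 then no longer passed. Glycolysis had 8 of 18 genes higher and none lower, with the same counts adjusted over the list alone, led by PFKP (11.7%), ALDOA (9.48%) and ENO1 (8.73%). Its median was 0.04 (0.04 to 0.06 with 1 library left out), at adjusted p = 1.69e-06 for the list and adjusted p = 0.0702 with an estimated correlation.

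Genes of lipid synthesis were lower. Of 12 tested genes of fatty acid synthesis 7 fell and none rose, with the same counts adjusted over the list alone and a median of -0.15 (adjusted p = 1.46e-09, and adjusted p = 0.0646 with an estimated correlation). SCD, which introduces the double bond into saturated fatty acids, fell by 13.1% (log2 change -0.20 ± 0.02 SE), the desaturase FADS1 fell by 11.3% and ACACA, which makes malonyl-CoA, fell by 14.5%. Of 23 genes of cholesterol synthesis and uptake 7 fell and 1 rose, NSDHL, with the same counts adjusted over the list alone; SQLE fell by 15.1%. The list had a median of -0.08 (adjusted p = 0.00362, and adjusted p = 0.180 with an estimated correlation). Of 8 liver X receptor targets 1 rose, APOE, also adjusted over the list alone; their median was -0.05, their mean was 0.05, and the test pointed down (adjusted p = 0.689).

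NF-kB and inflammatory genes were higher in part. Of 18 tested genes 8 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.14 (adjusted p = 9.39e-04, and adjusted p = 0.0702 with an estimated correlation). NFKB2 and RELB, which encode NF-kB subunits of the noncanonical pathway, rose by 34.8% (log2 change 0.43 ± 0.04 SE) and 38.3%, and the inhibitor NFKBIA rose by 25.8%. The 2 genes that fell were LIF and PTGS2. Antigen presentation had 8 of 13 genes higher and none lower (9 higher adjusted over the list alone), with a median of 0.17 (adjusted p = 5.32e-07, and adjusted p = 0.0702 with an estimated correlation). HLA-C rose by 19.0% and B2M, the light chain of class I molecules, by 11.7%. HLA genes are polymorphic and similar, so their single counts are uncertain. After the trend correction HLA-C was at a log2 change of 0.14, against 0.25 before, and 6 genes of the list were higher, with a median of 0.11. Interferon response genes did not move as a list (2 of 20 higher and 1 lower, the same adjusted over the list alone; adjusted p = 0.967), with ISG15 and IRF1 up by 26.4% and 17.9% and OAS3 down; the median was 0.02 while the test pointed down. ISG15 did not pass without rhSP-D replicate 3 (log2 change 0.31 against 0.34, adjusted p = 0.0516) or after the trend correction (log2 change 0.18, adjusted p = 0.243). IRF1 did not pass when the libraries were thinned to one depth (log2 change 0.15 against 0.24, adjusted p = 0.205).

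Of 14 complement and coagulation genes 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.04 (adjusted p = 0.00115, and adjusted p = 0.103 with an estimated correlation). C1S and C1R, proteases of the first complement component, rose by 14.2% and 15.1%, and C3 rose by 9.10%. TGF-beta targets had 8 of 16 genes higher and 1 lower, CTGF (8 and 2 adjusted over the list alone), with a median of 0.10 (adjusted p = 1.46e-09, and adjusted p = 0.0646 with an estimated correlation). PMEPA1 rose by 21.4% (log2 change 0.28 ± 0.02 SE), TGFBI by 12.3% and ID1, a helix-loop-helix inhibitor also induced by BMP signalling, by 16.4%; after the trend correction ID1 was at a log2 change of 0.08, against 0.22 before. YAP/TAZ targets had 4 of 12 genes lower and none higher, the same adjusted over the list alone, with a median of -0.06 (adjusted p = 0.0181, and adjusted p = 0.180 with an estimated correlation). TEAD1, CTGF and CRIM1 fell by 13.8%, 13.6% and 10.8%. The list did not pass without vehicle replicate 3 (adjusted p = 0.0558) or rhSP-D replicate 3 (adjusted p = 0.0521), with medians of -0.057 and -0.052, against -0.061.

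Airway secretory genes fell: of 7 tested genes 4 were lower and none higher, the same adjusted over the list alone, with a median of -0.14 (adjusted p = 1.17e-04, and adjusted p = 0.0702 with an estimated correlation). MUC5B, a gel-forming mucin and one of the more abundant transcripts, went from 5071 ± 44.1 to 4558 ± 158 CPM (SD, n = 3), and MUC5AC fell by 9.67% and the disulphide isomerase AGR2 by 14.9%. No gene of 7 tested alveolar type II markers passed, also adjusted over the list alone (adjusted p = 0.447 for the list). Of 6 tested alveolar type I markers 1 rose, EMP2 (2 adjusted over the list alone, and adjusted p = 0.435 for the list). Other members of the airway and alveolar lists were too scarce to test, so these results do not cover them. Among them were SFTPB, SFTPC and NKX2-1 of type II, PDPN and AQP5 of type I, and the secretory gene SCGB1A1. None of 8 SP-D binding proteins and receptors passed over all genes, and EGFR and LRP1 were lower adjusted over the list alone, at log2 changes of -0.10 and -0.11 (adjusted p = 0.204 for the list). After removal of the length and GC trends this list passed (adjusted p = 0.0384), but not with an estimated correlation as well (adjusted p = 0.142).

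Targets of p53 were higher: 7 of 21 rose and 1 fell, SESN2 (8 and 1 adjusted over the list alone), with a median of 0.13 (adjusted p = 3.32e-04, and adjusted p = 0.103 with an estimated correlation). PHLDA3, an inhibitor of AKT, rose by 29.03% (log2 change 0.37 ± 0.04 SE), BAX, a promoter of apoptosis, by 18.2% and CDKN1A, the cell cycle inhibitor p21, by 13.1%. With the length and GC trends removed BAX was at a log2 change of 0.14, against 0.24 before, and CDKN1A at 0.09, against 0.18. Of the list 5 genes were then higher and 2 lower. Apoptosis regulators went both ways, with 2 of 19 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.967); CASP9 rose by 17.0%, while MCL1 fell by 7.26% and PMAIP1 by 15.1%. PMAIP1 lost its call without vehicle replicate 2 (adjusted p = 0.0744), vehicle replicate 3 (adjusted p = 0.0726) or rhSP-D replicate 1 (adjusted p = 0.103), and when thinned (adjusted p = 0.115), but its log2 change of -0.24 stayed between -0.22 and -0.20. The median of the apoptosis list was 0.004 and its mean -0.01, and the test pointed down.

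S phase genes were lower in part, with 5 of 23 lower and 1 higher, the same adjusted over the list alone, and a median of -0.04 (adjusted p = 0.0401, and adjusted p = 0.180 with an estimated correlation). MCM4, a subunit of the replicative helicase, fell by 13.3% and UHRF1 by 14.1%, whereas PCNA rose by 9.25%, a call that ended after the trend correction. The list did not pass without vehicle replicate 2 (adjusted p = 0.136) or rhSP-D replicate 2 (adjusted p = 0.0575), with medians of -0.02 and -0.04. With the trends removed its median was -0.08, with 3 genes lower and none higher. Of 22 genes of G2 and mitosis 4 fell and none rose (4 lower and 1 higher adjusted over the list alone), and the list just missed the threshold (adjusted p = 0.0505). MKI67, the proliferation marker, fell by 11.7%, CENPF by 8.49% and CENPE by 12.9%, and the calls of CENPF and CENPE ended after the trend correction (adjusted p = 0.549 and 0.328). CENPF lost its call without vehicle replicate 3 (adjusted p = 0.0507), and CENPE without vehicle replicate 2 (adjusted p = 0.118), vehicle replicate 3 (adjusted p = 0.107), rhSP-D replicate 1 (adjusted p = 0.214) or rhSP-D replicate 3 (adjusted p = 0.0920). Without these libraries CENPF was at -0.11, against -0.13, and CENPE at -0.20 to -0.14, against -0.20. Of 28 early response and feedback genes of EGFR and ERK 6 fell and 2 rose, IER3 and JUNB (7 and 3 adjusted over the list alone; adjusted p = 0.0963 for the list), with EGR1 and FOS down by 11.1% and 10.3% and IER3 up by 22.2%. The log2 change of IER3 went from 0.29 to 0.15 after the trend correction. With the trends removed, the EGFR and ERK list (adjusted p = 2.21e-05) and that of G2 and mitosis (adjusted p = 0.0134) passed as lower; with an estimated correlation as well, the first was just under the threshold (adjusted p = 0.0484) and the second did not pass (adjusted p = 0.101).

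Epithelial and mesenchymal markers did not pass as lists in the main test. Of 16 epithelial junction and keratin genes 2 rose and 1 fell (2 and 2 adjusted over the list alone; adjusted p = 0.714), with KRT7 up by 11.5%, TJP1 down and KRT18 up by 3.45%. KRT18 turned to a log2 change of -0.02 after the trend correction and did not pass under scaling by library totals alone (0.008, adjusted p = 0.732). It also did not pass without vehicle replicate 1 (adjusted p = 0.0665), vehicle replicate 3 (adjusted p = 0.0695) or rhSP-D replicate 1 (adjusted p = 0.0936). Its log2 changes there were 0.046, 0.045 and 0.040, against 0.049. Of 16 genes of epithelial-mesenchymal transition 3 rose and 1 fell (3 and 2 adjusted over the list alone; adjusted p = 0.244). The median of this list was 0.10, and it passed as higher under fry, a test of the list by itself (adjusted p = 0.00527). VIM rose by 7.15% and S100A4 by 14.95%, and FN1 fell by a log2 change of -0.11. The trend correction ended the calls of S100A4 and FN1. Of 14 genes of matrix remodelling 3 rose, among them TIMP1 by 15.6% and MMP7 by 23.3%, and 2 fell, ADAM9 and ADAM10 (6 and 3 adjusted over the list alone; adjusted p = 0.0629, and adjusted p = 0.00561 with the trends removed, or 0.206 with an estimated correlation as well). TIMP1 was then at a log2 change of 0.08, against 0.21 before.

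Among stress responses, 6 of 14 heat shock genes rose and 1 fell, HSPH1 (7 and 1 adjusted over the list alone; adjusted p = 3.32e-04, and adjusted p = 0.103 with an estimated correlation), with HSPA8 up by 9.68%, HSPA1A by 12.5% and HSPA1B by 10.2%. After the trend correction 1 heat shock gene was higher, and the calls of HSPA1A and HSPA1B, whose sequences are almost the same, ended. Unfolded protein response genes went both ways, with 2 of 19 higher and 5 lower (3 and 7 adjusted over the list alone; adjusted p = 0.108); TRIB3 fell by 9.53% and EDEM1 by 12.1%, and ATF4 rose by 8.19%, a call that the correction ended. Of 17 genes of the ATF4 amino acid response 2 rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p = 0.132), among them SLC7A11, the cystine transporter, down by a log2 change of -0.22, STC2 down by -0.18 and PHGDH up by 0.13. With the trends removed these lists passed as lower (adjusted p = 2.38e-04 and 7.00e-04), but not with an estimated correlation as well (adjusted p = 0.103 and 0.142). NRF2 targets had 9 of 23 genes higher and 4 lower (9 and 8 adjusted over the list alone; adjusted p = 0.0811), including HMOX1 up by 18.5% and AKR1C1 up by 14.1%, the latter with close paralogs. With the trends removed 5 were higher and 6 lower, with a median of -0.008 (adjusted p = 0.429). Lysosome and autophagy genes had 8 of 18 higher and none lower (10 higher adjusted over the list alone; adjusted p = 4.01e-05, and adjusted p = 0.103 with an estimated correlation), with GABARAPL1 up by 15.9% and the cathepsins CTSB and CTSA up by 9.92% and 9.60%.

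The remaining lists did not pass. Of 15 hypoxia genes 1 rose, ADM, and 1 fell, EGLN3 (adjusted p = 0.967), of 6 aryl hydrocarbon receptor targets 1 rose, ALDH3A1, and 1 fell, CYP1B1 (adjusted p = 0.435), and none of 8 histone genes passed (adjusted p = 0.630). Adjusted over the list alone, the counts were 1 and 1 for hypoxia, 1 and 2 for aryl hydrocarbon receptor targets and 0 for histones. Markers of other cell types were mostly near 0 CPM. No gene of 4 tested fibroblast markers passed, also adjusted over the list alone (adjusted p = 0.608). CD68, which epithelial lines also express, rose by 8.94% as 1 of 2 tested macrophage markers (1 higher and 1 lower adjusted over the list alone), EGFL7 rose by 13.6% as 1 of 2 tested endothelial markers (1 adjusted over the list alone), and the single tested lymphocyte marker, CD79A, did not pass, also adjusted over the list alone; these 3 lists were too short to test.

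**Figure D2:**
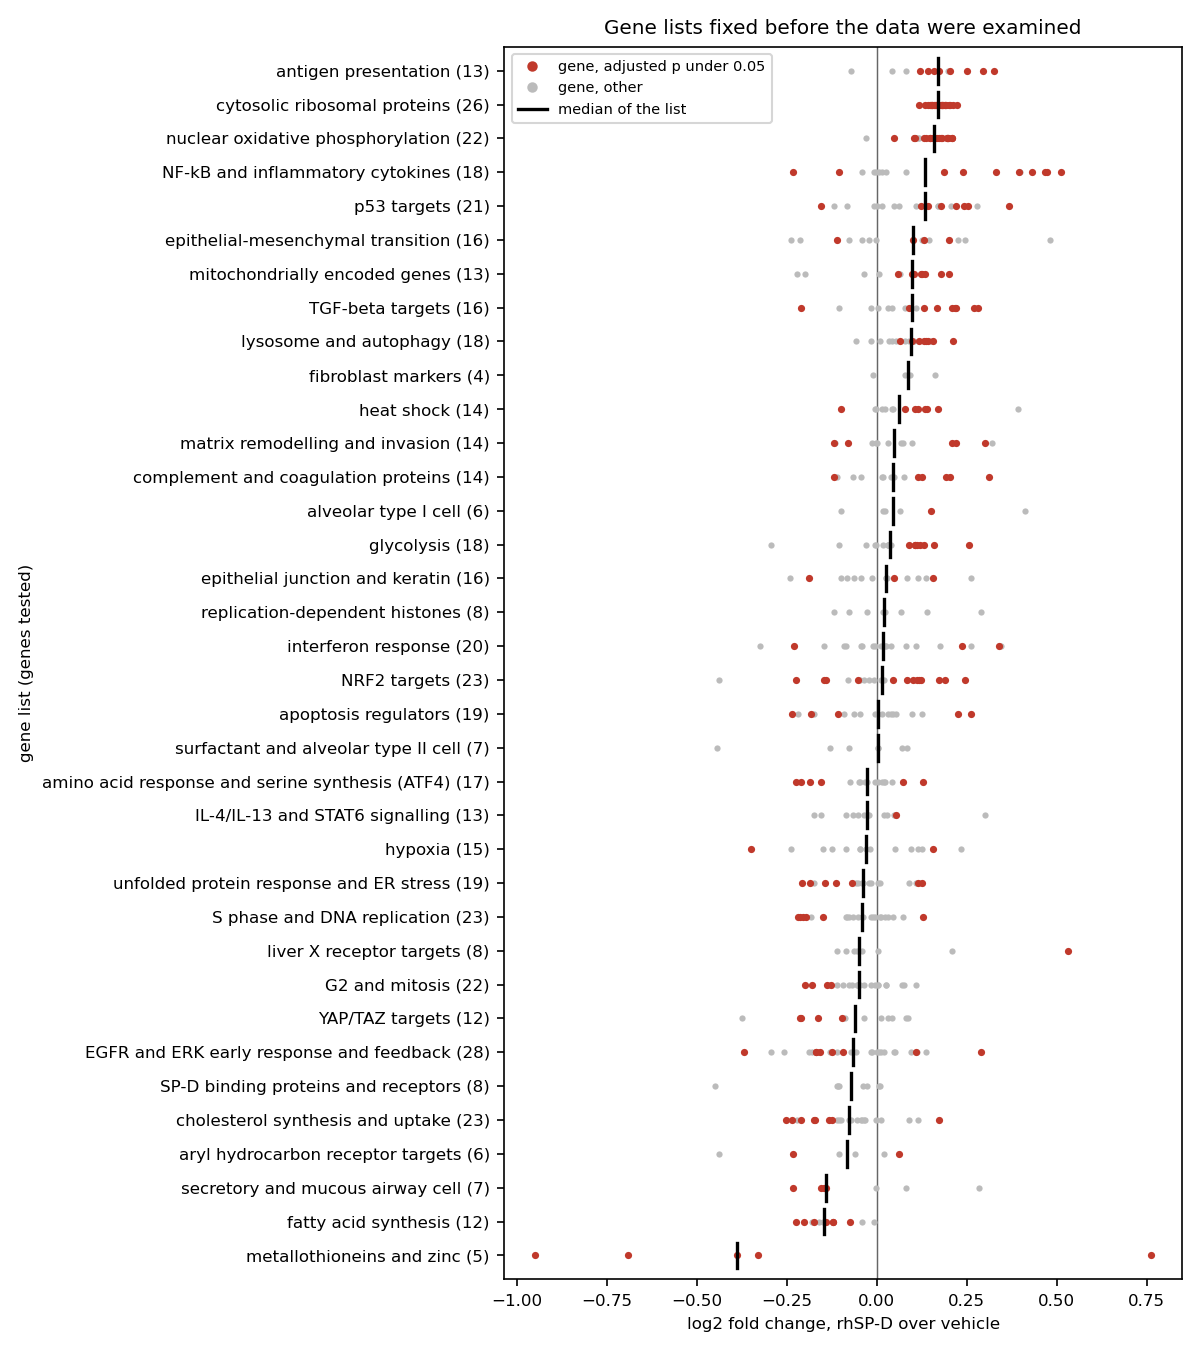
Log2 fold change of rhSP-D over vehicle (horizontal axis) for the genes of 36 lists (vertical axis, with the number of genes tested); each point is a gene, coloured where its adjusted p was under 0.05, and the bar is the median of the list. All 26 ribosomal protein genes lie above 0, all but SLC39A10 of the zinc list lie below 0, and the medians of the other lists lie between -0.15 and 0.17.

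The largest changes among genes of at least 1 CPM were in scarce transcripts. The 10 largest rises had mean levels from 1.01 to 5.91 CPM, and 2 of them were protein-coding genes: ST6GALNAC2, a sialyltransferase, which rose by 84.4% (log2 change 0.88 ± 0.15 SE), and DND1, which overlaps exons of the opposite strand. The others, ARAP1-AS1, CTD-2184D3.6, RP3-337H4.9, AC002398.13, AP001046.5, RP11-631M6.2, RP11-110I1.6 and AC117834.1, rose by log2 changes from 0.83 to 1.33. Among these 10 genes 7 lost their call when 1 or another library was left out, at log2 changes that were still 0.59 to 1.25. Of the 9 with a corrected value 6 lost their call after the trend correction, although their log2 changes of 0.87 to 1.03 shrank little, to between 0.74 and 0.93. The 10 largest falls, TP53TG3B, CTD-2303H24.2, ACSBG1, FAM115B, AC087645.1, PHC1P1, KLHL11, MT1F, ZBED6 and RP11-274B21.1, had mean levels from 1.09 to 3.34 CPM and log2 changes from -1.34 to -0.88. Of these 6 lost their call when 1 or another library was left out, at log2 changes that were still -1.15 to -0.73, and none of the 9 with a corrected value did so after the correction. Over both sets, calls of 7, 9 and 12 genes ended without vehicle replicates 1, 2 and 3, and of 8, 3 and 11 without rhSP-D replicates 1, 2 and 3. Several are pseudogenes or members of duplicated families. ARAP1-AS1, CTD-2184D3.6, RP3-337H4.9, AC002398.13, RP11-110I1.6 and DND1 overlap exons of the opposite strand over most of their exon length. Reads of all these genes cannot be assigned with certainty.

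Fold changes followed gene length and GC content. Over 10231 genes the median log2 change went from 0.16 for genes under 1000 nt of exon sequence to -0.08 for genes over 10000 nt, and from -0.07 for genes under 40% GC to 0.07 for genes over 60% GC. Library slopes were fitted on length and GC content together, to each library's deviation from the mean of all libraries. Per doubling of exonic length, they were 0.024 ± 0.003 in vehicle and -0.024 ± 0.006 in rhSP-D (SD, n = 3), with no overlap. The opposite signs of the group means are by construction, so only the difference between groups can be read from these trends. Of the 2482 changed genes with a corrected value, 1124 kept their call and 1358 did not when these trends were removed, an alternative chosen after seeing the data. Of 78 list members set by rule to be named, 27 had a change more than 1.5 times smaller after the correction, and 16 of these kept their call, among them KRT7, TJP1, SLC7A11, HMOX1, ALDOA, MT-ND3, MT-CYB and TEAD1. RN7SL1 and RN7SL2 are RNAs of the signal recognition particle. Scaled to library totals, they were together at 193, 240 and 314 CPM in vehicle replicates 1, 2 and 3. In rhSP-D replicates 1, 2 and 3 they were at 410, 347 and 378 CPM, so the groups did not overlap. Within each group, however, the level rose with the total count of the library. Across groups, rhSP-D replicate 2 was above vehicle replicate 3 at a lower total count (18599955 against 19803697). Depth was unequal between the groups, so this difference cannot be assigned to the treatment.

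**Figure D3:**
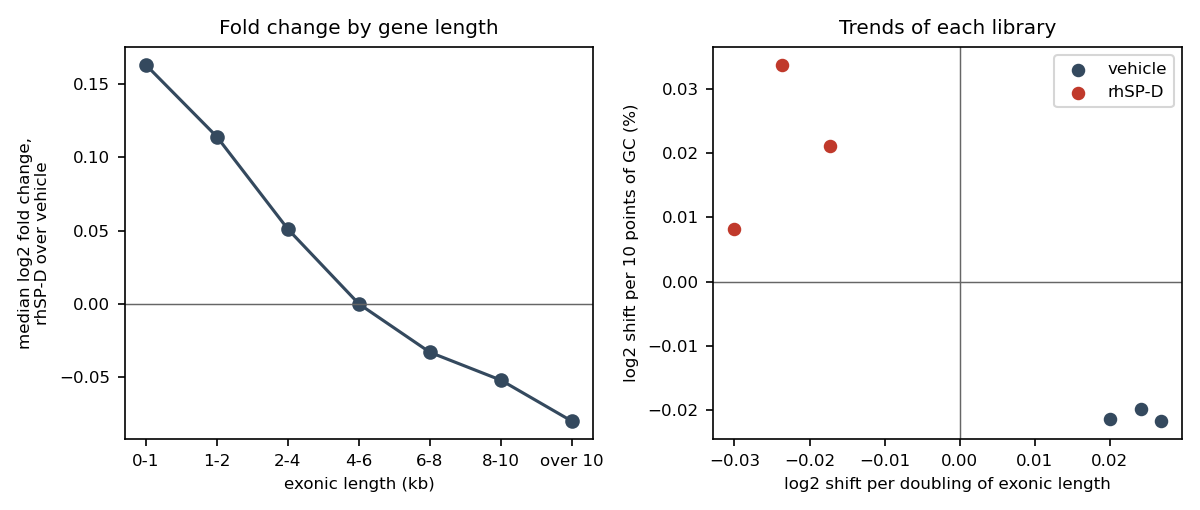
Left, median log2 fold change of rhSP-D over vehicle against exonic length in kb for 10231 genes with an average log2 CPM above 3. Right, for each library, the log2 shift per 10 points of GC content against the log2 shift per doubling of exonic length. Shifts are relative to the mean of all libraries, so the group means have opposite signs by construction. The median falls from 0.163 in the shortest class to -0.080 in the longest, and the 3 vehicle and 3 rhSP-D libraries lie in opposite corners.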

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

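The length and GC correction, alone or with an estimated correlation, and the thinning were tests chosen after seeing the data; the other alternatives were planned. The count of 2526 changed genes lay between 2294 and 2632 under DESeq2 size factors, upper-quartile factors, no filter, a 1 CPM filter, limma-voom and the replicate block. Library totals alone gave 2817 genes, 856 higher and 1961 lower. Leaving out 1 library gave 1678 to 2182 genes, 1042 to 1336 higher and 636 to 892 lower, with the lowest counts without rhSP-D replicate 1; without vehicle replicate 3 there were 1710, of which 643 were lower. The DESeq2 Wald test called 1534, of which 518 were lower, and gave an adjusted p to 7859 genes. Genes without one could not be called, but whether this lowered the count was not tested. The length and GC correction gave 1437 (782 higher, 655 lower), of which 1124 were among the 2526, and thinning gave 1927, of which 1774 were. An adjusted p under 0.01 left 1465 (939 and 526), a fold of at least 1.5 left 70 (28 and 42), and the test against a 1.2-fold change left 6 (3 and 3), by construction.

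Of the lists 17 passed, 16 to 20 with 1 library left out, 21 under library totals alone and 20 without a filter. After the length and GC correction 22 passed, and with an estimated correlation 0 passed. The estimate was -0.037 for the NF-kB list and -0.036 for the zinc list, below the preset 0.01. Spread shared by genes of a list therefore does not account for those lost calls. In simulated counts drawn gene by gene, the ribosomal list was shifted by a log2 change of 0.1. Its camera adjusted p was 8.15e-84 at the preset correlation and 0.0017 with an estimated correlation. The estimated setting thus gave a larger p-value also where genes shared no spread. With the length and GC correction and an estimated correlation together 7 passed, all at an adjusted p of 0.0484. Fry, which tests each list by itself and not against other genes, passed 24, gaining SP-D binding proteins, alveolar type I, EGFR and ERK, G2 and mitosis, epithelial-mesenchymal transition, matrix remodelling and NRF2 targets. Apart from the estimated correlations, the lists that passed kept direction and call in 249 of 255 values; 5 others, for S phase and YAP/TAZ, missed the threshold without 1 library or when thinned, and the mitochondrially encoded list turned to -0.0054 under the length and GC correction with either correlation. SFTPD, STAT6 and IL4R never passed, and their signs were not stable: SFTPD ranged from -0.26 to 0.22 with 1 library left out (-0.037 without vehicle replicate 1) and was -0.0668 after the correction, STAT6 ranged from 0.006 to 0.04 and was -0.0119 under library totals alone, and IL4R ranged from 0.001 to 0.04 and was -0.0199 under library totals and -0.0162 after the correction. Among 1573 values of genes set by rule to be named, 1467 kept direction and call, 105 lost the call, and KRT18 turned to -0.022 after the correction. The cause of these turns was not tested.

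Among lists that did not pass, the direction of the test turned in several settings, with medians near 0. Under library totals alone the epithelial list was -0.014, interferon -0.0227 and NRF2 targets -0.0251. Without a filter apoptosis was 0.0045, interferon 0.0286 and hypoxia -0.0242; under fry they were 0.0036, 0.0182 and -0.0291. With 1 library left out, apoptosis ranged from -0.0166 to 0.0155, interferon from -0.0367 to 0.0548, hypoxia from -0.0439 to -0.0031 and fibroblast markers from 0.0032 to 0.1295. After the correction, with either correlation, apoptosis was 0.021, the epithelial list -0.0129, hypoxia 0.015 and histones -0.0921; after thinning apoptosis was 0.0256 and interferon 0.1104. In some of these the median and the test differ in sign.

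The replicate number as a block gave 2319 genes, and 17 lists. Same-numbered samples did not deviate together, with correlations of -0.079, -0.068 and 0.027, so the numbers were not taken to pair the samples. By depth, a 1.1-fold change was recovered in 14% of simulated genes, so unchanged calls do not exclude small changes.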

Other observations

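Tests of the length and GC trend, of terminal oligopyrimidine transcripts and of zinc availability were chosen after the results were seen; those of other splits, depth, matched lists and glucocorticoid targets were set before. Outside the fixed lists, and chosen after their values were seen, several abundant transcripts changed. AKR1B1, aldose reductase, rose by 19.2% (1670 ± 10.9 to 1992 ± 21.04 CPM, SD, n = 3), the sodium pump subunit ATP1B3 rose by 23.8%, the testis-enriched chaperone gene HSPA2 by 29.2%, the ephrin EFNA1 by 31.4%, COL7A1, which encodes the collagen of anchoring fibrils, by 17.4%, and the keratin KRT81 by 14.7%, whose log2 change fell from 0.20 to 0.08 with the length and GC trends removed. NEAT1, the long non-coding RNA that builds paraspeckles, fell by 14.7% (1345 ± 17.7 to 1147 ± 24.7 CPM), CPS1, the first enzyme of the urea cycle, fell by 12.5% (log2 changes of -0.23 and -0.19, or -0.13 and -0.12 with the trends removed), and GPCPD1, a glycerophosphocholine phosphodiesterase, fell by 20.6%. TSC22D3, a glucocorticoid-induced gene, fell by 17.0%.

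The first pattern weighed is the 2526 changed genes. The real split gave more genes than the other splits of the 6 samples (1 of 10 gave as many; the highest other gave 8), but 10 splits are too few for a share under 0.05. Against unequal depth as the cause, 1774 of these calls remained when the libraries were thinned to one depth. With the length and GC trends removed, 1124 of the 2482 calls with a corrected value remained, and 313 other genes passed. The trends as fitted, on merged exon length and GC content of the longest transcript, were therefore not the whole cause. A trend on the length of expressed transcripts may have been removed only in part, so it was not excluded. The 1358 calls that ended had a median size of 0.155 before and 0.076 after, with a median SE of 0.04 both times. At the median the change shrank and the SE did not, though 6 of the largest rises lost their call with little change in size. The 1358 were picked for having lost their call, which by itself favours a smaller change, so no cause can be read from this. Whether those calls reflect library preparation or the treatment cannot be told apart, because the slopes on length differed between groups by 9.3 within-group SDs and so followed the treatment in every library.

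The second pattern is the rise of all 26 ribosomal protein genes. With the length and GC trends removed the median of the list was 0.128, against 0.169 before. The median before removal lay at the 100th percentile of 10000 lists matched on expression, length and GC content. Those lists had a median of 0.075 and a highest median of 0.139. Both tests took length from the merged exons of a gene, 5894 nt for RPS3 and 3799 nt for RPS19. Merged exons can be longer than the transcript expressed, and genes under 1000 nt had a median of 0.163. The rise thus exceeded that of genes alike in merged length, but a trend on the length of expressed transcripts was not excluded. A candidate explanation is a shared rise of transcripts with a terminal oligopyrimidine motif, the class that mTOR signalling regulates. The 15 non-ribosomal genes of that class had a median of 0.097 before the correction and 0.103 after it. Before it 12 of 15 rose (camera p = 6.56e-15, and p = 0.0164 with an estimated correlation). The correction used merged exon lengths, so it cannot separate such a rise from a trend on the length of expressed transcripts. As a hypothesis found and tested on the same data, the explanation also leaves open whether synthesis, stability or library preparation moved these transcripts.

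The third pattern is lower metallothioneins and SLC30A1 with higher SLC39A10. Against the length and GC trends as its cause, all 5 tested genes of the list kept their call and direction with them removed. The median of the list, which is the value of MT2A, was -0.508, further from 0 than before. SLC39A10, MT1X and MT1F also moved away from 0, while SLC30A1 moved towards it, from a log2 change of -0.33 to -0.28. Lower glucocorticoid signalling, since glucocorticoids also induce metallothioneins, was left undecided: the median of 13 target genes was 0.059, above the bound of 0 set beforehand, but its interval ran from -0.259 to 0.191 and members went both ways, so the bound, which took no account of that spread, was set aside after the value was seen. Less zinc available to treated cells may produce this set of changes, since zinc induces metallothioneins and SLC30A1 (median -0.54 with 3 metallothioneins), but the test runs on the genes that raised the idea and zinc was not measured here. A difference in metal content between the protein and vehicle solutions was not tested.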
